A study of Ovis aries with 14 samples.

How the data were processed

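RNA from whole frozen ovaries of Suffolk sheep was sequenced in 14 samples: 3 control and 3 testosterone fetuses at day 90, and 4 control and 4 testosterone adults at year 2. Testosterone was given to the mothers between days 30 and 90 of gestation. Libraries were made from 500 ng of RNA and read as 150-base pairs, with 45 to 50 M reads per sample stated. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b, and the series text names DESeq2 for the comparison. The counting program, genome build and annotation version are not given in the sources used here.

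The authors deposited 3 tables, each with a signal column per library and columns of log2 fold change, p-value and adjusted p-value. The deposited signal is a DESeq2 normalized count, that is, reads per gene divided by a size factor for the library. In every library 100% of the values were whole multiples of 1 step, within 0.01 of a whole read, so reads were recovered by dividing by that step. The fetal table holds 3 controls against 3 testosterone samples. The first adult table holds controls 4, 5 and 6 against testosterone 4, 5 and 6, and the second holds controls 4, 6 and 7 against testosterone 5, 6 and 7. The labels list 4 adult controls while the series text counts 3 controls and 4 treated, and neither adult table holds those numbers. Because 4 libraries are in both adult tables, the 2 tables are not independent.

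Recovered depth ran from 22.6 to 33.4 M reads per library. Control 6 had 26.4 M reads in the first adult table and 33.4 M in the second. The smaller set behaved as a random part of the larger one, with 0 genes having more reads in it and a mean chi-square of 1.00 per gene, while control 4 and testosterone 5 and 6 were identical in both. Zero reads in a library were treated as up to 3 counts when a fold was given.

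Because the values are normalized, the main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2 of the value plus 1, for genes with a mean of at least 10, within each table, with Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) were run on the recovered reads. In the fetal data DESeq2 called many more genes than limma, and both are given. Each was tested on simulated data made from the libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In the fetal table limma recovered 74% and 99% with 13 false calls, DESeq2 82% and 99% with 46, and edgeR 76% and 99% with 14. In the adult tables limma and edgeR recovered 0% of either, and DESeq2 recovered 3% and 76% in the first with 55 false calls and 8% and 61% in the second with 63.

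There were 40 gene lists with 1036 different genes for cell types, pathways and RNA handling. Of these, 38 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The erythroid and platelet lists had fewer and were not tested. Genes were also adjusted over the list alone. The effect of testosterone was compared between ages by the difference of log2 changes with a moderated test, and calls at both ages by Fisher's exact test. Groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined.

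The rule named, for each comparison, up to 12 genes per direction past the threshold with no overlap between groups, or the genes of smallest p up to 5 per direction; members of a list that passed when adjusted over the list alone, up to 6 per list; up to 4 members of smallest p of a list that passed camera; 12 genes of steroid synthesis and reception wherever measured; and the 6 genes of smallest p for the difference between ages. Within the limit of 4, the number of camera list members given was set after the values were seen: up to 4 per list for the fetuses and the 1 of smallest p per list for the adult tables. Genes of smallest p were ranked among genes with a name only. Genes outside the rule are said to have been chosen after their values were seen, except ENSOARG00000020231, which passed the threshold but has no name. Of the genes the rule selects, 2 are not reported here.

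Alternatives set in advance were other filters, pseudocounts of 0.5 and 5, quantile normalization, DESeq2 and edgeR, other variance models, the sample number as a block, a threshold of 0.1, the other adult table, other list tests, and leaving out each library. Added after the data were seen were all 8 adult libraries joined through the recovered reads, alone, with number 7 as a batch, with the luteal list as a covariate and without control 4, the mixed form of fry, and the edgeR interaction between ages. Gene coordinates were not used, since the reference tables carry no matching gene identifiers.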

Results

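Ovaries of Suffolk sheep whose mothers received testosterone between days 30 and 90 of gestation were compared with ovaries of untreated controls at 2 ages, fetal day 90 and adult year 2. Values are normalized counts given as mean ± SD, and log2 changes are testosterone minus control. The p-values measure only the spread between these samples, because the labels number the samples without stating how they relate to mothers or litters.

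In the fetal ovary, CORIN, which encodes a membrane protease that activates natriuretic peptides, rose from 859 ± 188 in controls to 3642 ± 652 after testosterone (n = 3 per group, log2 change 2.09, SE 0.18, limma adjusted p = 0.0218). EFHB, a gene for an EF-hand protein, rose from 117 ± 8.67 to 418 ± 43.1 (log2 change 1.83, SE 0.16, limma adjusted p = 0.0218). PLCXD3, a gene of the phospholipase C family, fell from 334 ± 31.4 to 99.3 ± 10.1 (log2 change -1.74, SE 0.17, limma adjusted p = 0.0308). For each of these genes all 3 testosterone libraries lay on 1 side of all 3 controls. The genes of next smallest p did not pass with limma (adjusted p from 0.0554 to 0.105) and all passed with DESeq2. Among them, SPATA46 had means of 2.03 in controls and 33.5 after testosterone, LAMC3, a laminin chain, 2802 and 6588, and FIBIN 89.5 and 282. Lower after testosterone were CBLN2 (1665 and 838), ASIP, the agouti signaling protein (4630 and 1815), PNPLA1 (259 and 59.1) and CDH19, a cadherin (235 and 51.3).

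**Figure D1:**
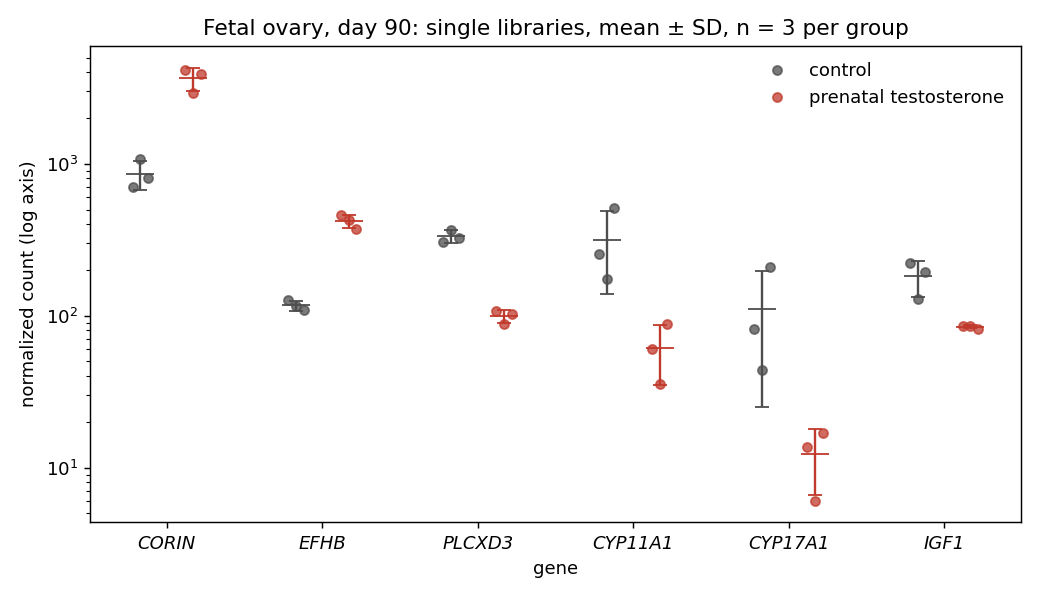
Normalized counts (log axis) of 6 genes in the 3 control and 3 testosterone fetal libraries, with points for single libraries and bars for mean ± SD. CORIN and EFHB were higher in every testosterone library, and PLCXD3, CYP11A1, CYP17A1 and IGF1 were lower.

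With limma, 2 genes rose and 1 fell among 16513 tested, and 1611 had an unadjusted p under 0.05 where chance gives 826. DESeq2 on the recovered reads called 177 higher and 84 lower, and edgeR 3 higher and 1 lower. The authors' deposited DESeq2 columns gave 178 higher and 84 lower, all 262 with the same sign in the limma fit. Both come from the same libraries, so the shared sign is no independent support. The groups did not overlap for 2699 genes, or 16.3%, against 10% by chance. Neither this excess nor that of small p was compared with other splits of the libraries. Controls 1 and 2 and testosterone 1 split from the rest gave 29 genes with limma and 264 with DESeq2, more than the real groups. Differences between samples other than treatment may thus add to both. The limma count was 0 without control 1, without testosterone 1 or without testosterone 2, 1 without control 2, and 13 without testosterone 3.

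Of the steroidogenesis list, 2 genes of androgen synthesis were lower after testosterone, while the list as a whole had a median log2 change of -0.029 (8 positive, 9 negative) and did not pass camera (adjusted p = 0.653). CYP11A1, the enzyme that starts steroid synthesis from cholesterol, had 314 ± 175 in controls and 61.3 ± 26.2 after testosterone (n = 3, log2 change -2.28, SE 0.44). CYP17A1, which makes androgen precursors, had 111 ± 85.9 and 12.3 ± 5.60 (log2 change -2.90, SE 0.59). Both fell when adjusted over the list alone, as the only 2 of 17 measured steroidogenesis genes, while over all genes their limma adjusted p was 0.223 and 0.237. DESeq2 adjusted p over all genes was 3.9e-05 and 2.4e-04. STAR, which carries cholesterol into mitochondria, had 837 ± 73.4 and 816 ± 143 (log2 change -0.05). Among receptors, ESR1 had 294 ± 31.1 and 233 ± 26.2, ESR2 684 ± 194 and 663 ± 212, and INSR 2336 ± 48.9 and 2827 ± 266. None of these 4 genes passed (limma adjusted p from 0.432 to 0.953). LHCGR, AMH, CYP19A1 and FOXL2 are not listed by name in the fetal file.

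Growth factor, matrix and contractile genes also passed when adjusted over the list alone, none of them over all genes with limma (adjusted p from 0.0809 to 0.353). In the insulin and IGF list, IGFBP2 and IGFBP6, which bind IGFs, rose by log2 0.39 and 0.51, while the growth factor IGF1 (log2 change -1.05, from 182 ± 48.1 to 84.8 ± 2.33) and IGFBP4 (-0.38) fell, 4 of 27 genes. In the protease list MMP9 (0.96), ADAMTS5 (1.26) and the inhibitor TIMP1 (0.30) rose and MMP15 (-0.38) fell, 4 of 21 genes. GDF10, a BMP family member, rose (1.64), as did the epithelial keratin KRT8 (0.91) and, among 15 smooth muscle markers, MYH11 (0.76), DES (0.55) and TAGLN (1.01). PRDX6, a peroxide-removing enzyme, rose (0.75) and GCLC, of glutathione synthesis, fell (-0.45). ADM, a vasodilator peptide induced by hypoxia (-0.66), and APAF1, a part of the apoptosome (-0.56), fell.

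Ribosomal protein genes moved as a group: all 33 measured had positive log2 changes (median 0.27), and 30 rose when adjusted over the list alone, 0 over all genes with limma (30 at an unadjusted p under 0.05, and 10 passed with DESeq2). Among those of smallest p were RPLP1 (0.30), RPL29 (0.32), RPS20 (0.31), RPS21 (0.30) and RPS19 (0.28). The list passed camera (adjusted p = 1.2e-24), and the adjusted p = 0.592 with an estimated correlation. Its median was 0.13 after quantile normalization.

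Camera also passed 5 other lists. Granulosa cell markers were higher (15 of 21 positive, median 0.30, adjusted p = 0.0012, and adjusted p = 0.592 with an estimated correlation), with means in controls and after testosterone of 7323 and 9740 for HSPB1, 161 and 247 for the activin-binding FST, 14.9 and 34.7 for the receptor FSHR, and 283 and 428 for MRO. Oxidative stress genes were higher (18 of 21 positive, median 0.13, adjusted p = 5.7e-04, and adjusted p = 0.592 with an estimated correlation), among them PRDX4 (log2 change 0.27) and HMOX1 (0.54). Nuclear-encoded oxidative phosphorylation genes were higher (22 of 26 positive, median 0.13, adjusted p = 3.1e-04, and adjusted p = 0.854 with an estimated correlation), with ATP5MC1 at 0.30, COX6B1 at 0.21, COX5B at 0.22 and COX4I1 at 0.18. Smooth muscle markers were higher (11 of 15 positive, median 0.14, adjusted p = 0.0280, and adjusted p = 0.854 with an estimated correlation), with ACTG2 at 0.72. The list means of the groups overlapped for smooth muscle, with control 1 at 0.058 and testosterone 3 at 0.0055 relative to the mean of the libraries. They also overlapped for oxidative phosphorylation (control 3 at 0.017 and testosterone 2 at 0.013). Germ cell and meiosis genes were lower (39 of 41 negative, median -0.41, adjusted p = 1.5e-04, and adjusted p = 0.854 with an estimated correlation), with MOV10L1 at -0.46, PRDM1 at -0.37, SMC1B at -0.56 and PIWIL2 at -0.49. The germ cell list varied within both groups: relative to the mean of the 6 libraries it stood at 0.37, 0.89 and -0.60 in controls 1, 2 and 3 and at 0.31, -0.38 and -0.58 in testosterone 1, 2 and 3. With fry, which asks whether a list moves 1 way on balance, 0 of 38 lists passed (3 at an unadjusted p under 0.05, smallest adjusted p = 0.152). Mixed fry, which asks whether the genes of a list move either way and was added after the data were seen, passed 8 fetal lists (smallest adjusted p = 0.0023): steroidogenesis, cholesterol, granulosa cells, the TGF-beta family, insulin and IGF, oxidative stress, hypoxia and ribosomal proteins. It passed 0 lists in either adult table (smallest adjusted p = 0.932 and 0.958). Without testosterone 3, camera passed 12 lists, and without control 1 or control 2 it passed 9.

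**Figure D2:**
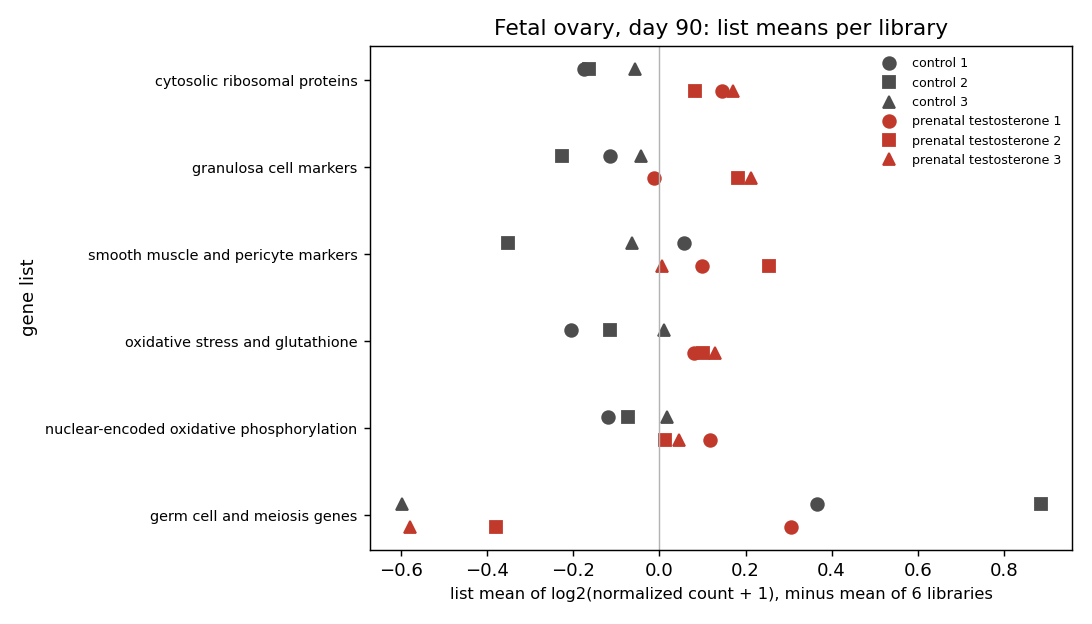
Mean of each of 6 gene lists in the 6 fetal libraries, as log2(normalized count + 1) relative to the mean of the 6 libraries, with circles, squares and triangles for numbers 1, 2 and 3. Ribosomal protein genes were higher in all 3 testosterone libraries, and germ cell genes spread from -0.60 to 0.89 among the controls.

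In the adult ovary, a gene with no name in the files, ENSOARG00000020231, rose from 454 ± 125 to 8029 ± 1002 in the first table (n = 3 per group, log2 change 4.17, SE 0.27, limma adjusted p = 0.0256) and from 491 ± 155 to 8313 ± 863 in the second (log2 change 4.13, SE 0.30, limma adjusted p = 0.0378). Across the 8 adult libraries it lay between 313 and 610 in controls and between 6994 and 9010 after testosterone. In the fetal libraries it lay between 4399 and 7600 in both groups. ENSOARG00000020142, chosen after its values were seen, had 59.9 ± 13.2 in the 4 adult controls and 0 reads in all 4 testosterone libraries, at least 19.9-fold lower against a floor of 3 counts per library. With edgeR the adjusted p of ENSOARG00000020231 was 0.0822 and 0.124, and leaving out any 1 library of either table left 0 genes past the threshold with limma, while its log2 change stayed between 3.92 and 4.32 in the first table and between 3.84 and 4.31 in the second. With all 8 adult libraries joined, a fit added after the data were seen, its adjusted p was 5.1e-04 with limma and 0.0017 with edgeR. With the sample number as a block in that limma fit it was 0.0978. The result for ENSOARG00000020142 depended on the tool: in the joined fits its adjusted p was 0.0135 with limma, 2.1e-09 with DESeq2 and 0.178 with edgeR. In the joined limma fits it was 0.0531 with number 7 as a batch. There it also did not pass without control 4 or with the sample number as a block. Within either adult table alone ENSOARG00000020142 did not pass with limma, while the authors' deposited columns called it in both.

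**Figure D3:**
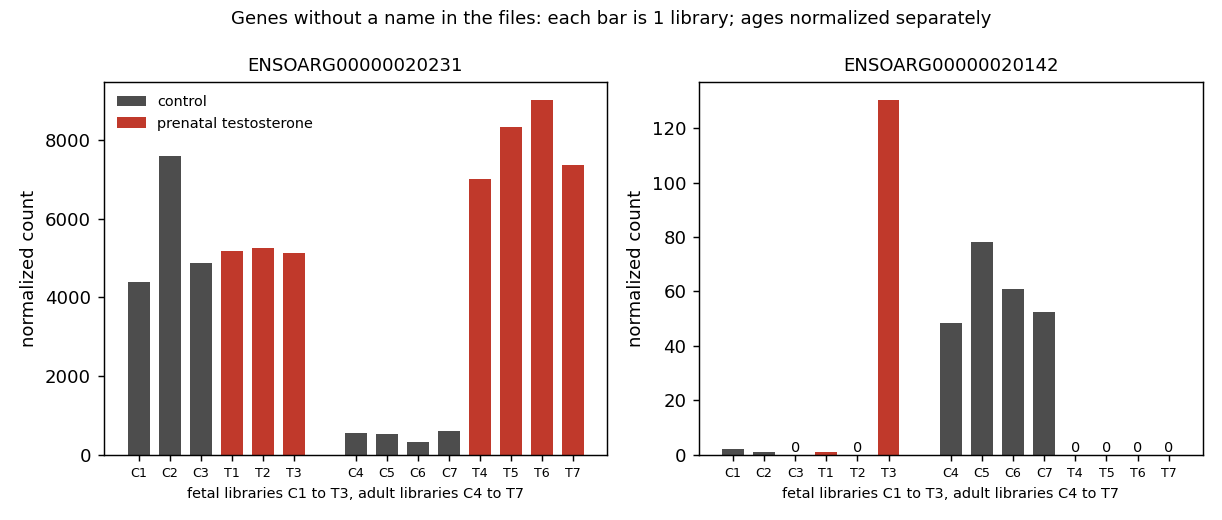
Normalized counts of ENSOARG00000020231 and ENSOARG00000020142 in the 6 fetal and 8 adult libraries, with 1 bar per library and the ages normalized separately. In adults the first was between 6994 and 9010 after testosterone and between 313 and 610 in controls, and the second was at 0 in all 4 testosterone libraries.

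No named gene passed with limma in either adult table. The genes of smallest p in the first table included CORIN, with 228 ± 112 in controls and 779 ± 377 after testosterone, TMSB15A (1.75 and 21.8), ENPP6 (348 and 999), SOLD1 (43.0 and 94.5) and LRRN3 (201.2 and 551), and, with lower values, the matrix factor CTGF (9529 and 3162), CLCA2 (373 and 18.8), ANKRD55 (836 and 316), the chitinase-like CHI3L1 (7117 and 2343) and CPVL (25.7 and 2.79). In the second table they were CFAP58, a cilium gene (5.89 and 61.0), the growth factor NRG2 (135 and 337), TMSB15A (2.27 and 21.9), DSEL (1441 and 2331) and TENM1 (86.4 and 279), and, with lower values, the immediate early gene FOS (4248 and 1162), TNK1 (149 and 45.7), SLC51B (41.8 and 1.39), ALDH1A3, of retinoic acid synthesis (933 and 519), and MOXD1 (113 and 32.0). DESeq2 called CLCA2 in the first table (adjusted p = 0.0088) and CFAP58 in the second (adjusted p = 0.0080). Among the steroid genes and receptors fixed in advance, log2 changes in the first table ran from -0.81 for STAR to 1.88 for FSHR, with SE from 0.44 for ESR1 to 2.66 for CYP17A1. In the first and second tables INSR had log2 changes of 0.51 and 0.44, ESR2 of 0.65 and 1.005, and CYP11A1 of -0.25 and -0.40, none past the threshold. The direction of CYP11A1 turned with DESeq2 (0.31 and 0.41) and with edgeR (0.32 and 0.46). In the first table STAR was at 0.57 without control 6 and FSHR at -0.37 without control 4.

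With limma 1 gene rose and 0 fell among 15856 tested in the first table and among 16064 in the second, with 101 and 78 genes at an unadjusted p under 0.05, where chance gives 793 and 803. DESeq2 called 2 higher and 2 lower in the first and 3 higher and 2 lower in the second, the same counts as in the authors' deposited columns, and edgeR called 0 in both (163 and 151 at an unadjusted p under 0.05). The groups did not overlap for 3.57% and 2.61% of genes, against 10% by chance. In simulated data limma recovered 0% of 4-fold changes in the adult tables and 99% in the fetal table, so adult changes of that size were not detectable with it.

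The adult libraries differed from each other far more than the groups did, in genes of the corpus luteum, the follicle and smooth muscle. These genes were chosen after their values were seen. OXT, made by luteal cells in sheep, had 94884 in control 6, 110586 in testosterone 4 and 61705 in testosterone 7, and between 22.3 and 80.2 in the others. STAR had 36624, 35001 and 49611 in the same libraries and between 584 and 3396 elsewhere, and CYP17A1, expressed by theca cells, had 1.62, 15.3 and 5.67 there and between 183 and 2811 elsewhere. The mean of the luteal list differed by 0.64 between testosterone and control (exact permutation test, 4 against 4, two-sided p = 0.83, the smallest possible being 0.0286). Control 4 had 278273 for MYH11 and 95832 for DES, against at most 111582 and 8133 elsewhere. Correlations between libraries ran from 0.838 to 0.975 in adults and from 0.971 to 0.985 in fetuses.

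**Figure D4:**
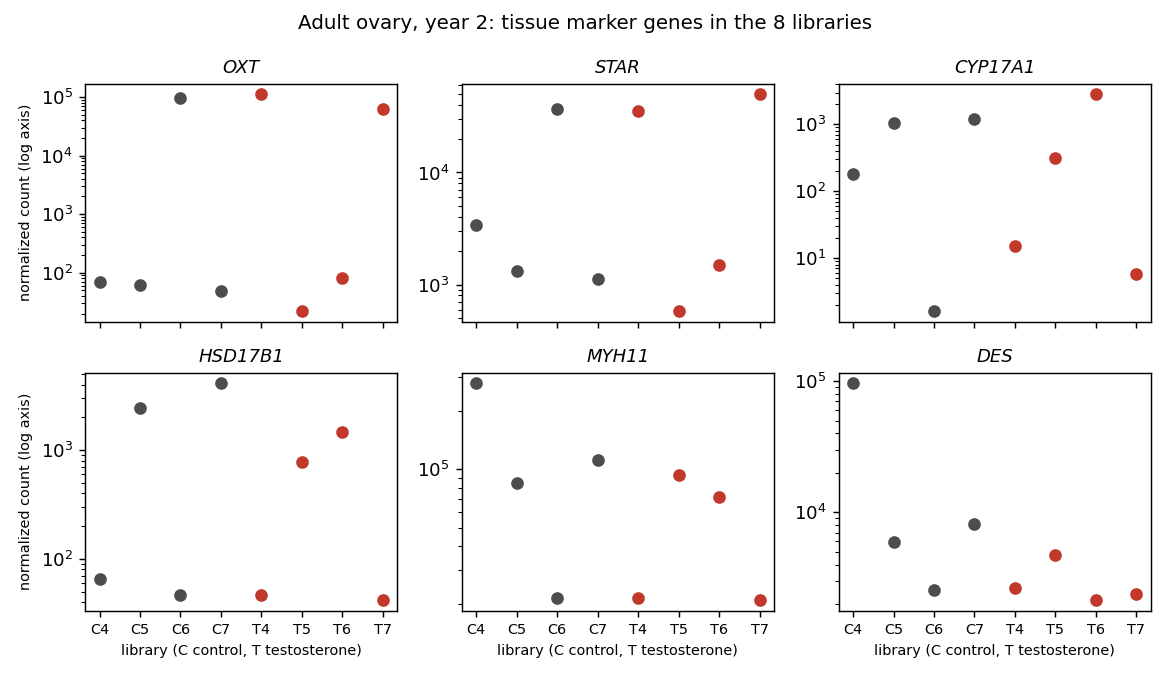
Normalized counts (log axis) of 6 marker genes in the 8 adult libraries, with 1 point per library, gray for controls and red for testosterone. OXT was at least 61705 in control 6, testosterone 4 and testosterone 7 and was at most 80.2 elsewhere, and DES reached 95832 in control 4.

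In the 2 adult tables several gene lists passed camera, most of them lower after testosterone, in libraries that stood apart in the same genes. Smooth muscle markers were lower in both tables (median -0.74 and -0.85, adjusted p = 9.1e-04 and 4.0e-05), with DES at log2 -1.92 and -2.12. Without control 4, DES was at -0.38 and -0.65. Endothelial markers (median -0.44 and -0.57, with SOX17 at -0.82 in the first table and PLVAP at -1.49 in the second), immediate early genes (-0.34 and -0.70, with CYR61 at -1.29 in the first), oxidative phosphorylation genes (-0.16 and -0.26, with UQCRC1 at -0.30 in the first and ATP5MC1 at -0.49 in the second) and angiogenic factors (-0.33 and -0.37, with PDGFC at -0.43 and NOTCH4 at -0.58) were also lower in both. Control 4 was the highest library for smooth muscle, endothelial and angiogenic lists, and without it SOX17 was at -0.19, PLVAP at -0.63 and CYR61 at -0.58. In the first table alone, lists of epithelium (all 17 negative, median -0.88, with CAPS at -1.37), extracellular matrix (-0.37), proteases (-0.30, with ADAMTS5 at -0.85), inflammation (-0.41, with IL1B at -2.11), interferon response (-0.27, with CXCL10 at -0.57), complement (-0.48, with F3 at -0.81) and lymphocytes (-0.24, with CD8A at -0.56) were lower, and germ cell genes (0.28, with SYCE2 at 0.85) and steroid receptors and cofactors (0.17, with NRIP1 at 0.55) were higher. The interferon list went the other way in the second table, with 20 of 22 genes positive (median 0.26), and did not pass there. For all of these lists the adjusted p = 0.903 in the first table and adjusted p = 0.982 in the second with an estimated correlation, and fry passed 0 lists, also at an unadjusted p under 0.05. Of 38 lists, 14 passed in the first table, but 7 without control 4 and 3 without testosterone 6. In the second, 5 passed, and leaving out 1 library passed 8 (control 6), 9 (testosterone 6), 10 (testosterone 5), 12 (control 4), 14 (control 7) or 19 (testosterone 7). With all 8 adult libraries joined, a fit added after the data were seen, 7 passed, 3 of them higher after testosterone and 4 lower. Higher were the lists of macrophages (all 21 positive, median 0.78), steroidogenesis (median 0.48) and interferon response (median 0.44, with testosterone 7 at 1.87 above the mean of the libraries). The macrophage list stood highest in the libraries high in OXT, control 6, testosterone 4 and testosterone 7 (2.03, 1.97 and 2.31 relative to that mean). So did the steroidogenesis list (0.60, 1.04 and 0.62). Control 6 is the only control among them. In the first table the macrophage list had a median of -0.31, with 15 of 21 negative. Of the lists lower in both tables, endothelial, immediate early and oxidative phosphorylation genes had medians of -0.15, -0.050 and -0.021 in the joined fit and did not pass camera (adjusted p = 0.652, 0.759 and 0.842). For the 7 lists that passed the adjusted p = 0.943 with an estimated correlation, and fry passed 0 lists, also at an unadjusted p under 0.05.

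The effect of prenatal testosterone was then compared between the ages. The difference, adult minus fetal log2 change, was ranked by p among genes with a name, so ENSOARG00000020231 was left out of the ranking. With the first adult table, DOK5 (-1.59), the protease ADAMTS5 (-2.11), PLCXD3 (2.89), the stress gene GADD45G (-1.50), MOXD1 (-3.05) and DSEL (1.05) came first. With the second, CFAP58 (3.68), DOK5 (-1.54), DSEL (1.13), MOXD1 (-2.92), CSDC2 (-1.14) and GGT7 (1.295) did. None passed: the limma difference gave 0 genes with either table, and 236 of 15222 and 170 of 15298 had an unadjusted p under 0.05, where chance gives 761 and 765. An edgeR interaction, added after the data were seen, called 1 gene with each table, ENSOARG00000020231 (4.27, adjusted p = 0.0018, and 4.25, adjusted p = 0.0039). It estimates the spread of a gene over both ages together, while the adult libraries varied more than the fetal ones. The spread in adults may thus be understated, and edgeR within either adult table alone called 0 genes. The limma count was 1 for the first table without fetal control 2.

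No gene passed at both ages. At an unadjusted p under 0.05, 7 genes were higher at both ages with the first adult table (CORIN, LRRN1, COL6A5, LRFN5, GPR22, TENM1 and TMSB15A), where independent lists give 2.57 (Fisher's exact test, two-sided p = 0.0132), and 2 were lower, where they give 2.28 (exact p = 1). With the second, 9 were higher, where 2.12 are given by independent lists (exact p = 1.9e-04), and 3 were lower, where 1.51 are (exact p = 0.192). With all 8 adult libraries 6 genes were higher at both ages (exact p = 0.140). TENM1 and TMSB15A were among the higher genes each time, and CORIN only with the first table: in adults it had 170 in testosterone 7 and 285, 305 and 250 in controls 4, 5 and 7. Fetal and adult log2 changes had a Pearson correlation across genes of -0.03 and -0.06 and a Spearman correlation of -0.11 and -0.11, and genes are not independent replicates.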

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

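Chosen only after the result was seen were the edgeR interaction, the joining of all 8 adult libraries, mixed fry, and the tests of a number 7 batch, of the treatment as the whole cause, of listed cell types, of an inherited variant, and of steroidogenic cells, single libraries and scaling.

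Among 91 gene-by-group sets of 4 adult libraries, 12 held a library far from the other 3, each time with a higher value. Independent, normally distributed values would give 4.55, but that is no fair baseline here. The counts were not logged, the sets share libraries, and most genes were picked by their p within a single adult table. The 12 are therefore only a description. Control 4 stood apart for DES (95832), CYR61 (9354) and ESR1 (1450), control 6 for STAR (36624) and CYP11A1 (37534), and control 7 for SYCE2 (94.5). Testosterone 4 stood apart for FOS (5306), SLC51B (29.7) and PLVAP (1458), testosterone 6 for CYP17A1 (2811), and testosterone 7 for CPVL (43.1) and CXCL10 (1947). The effect of testosterone on ENSOARG00000020231 differed between ages by a log2 of 4.27 with the first adult table, 4.25 with the second and 4.16 with all 8 adult libraries by edgeR interaction, and by 4.11 with all 8 by limma (adjusted p = 0.0081).

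Of 13 luteal genes, 7 were higher in each of control 6, testosterone 4 and testosterone 7 than in all other adult libraries, 1 (PTGS2) was lower there and 5 did neither. As the source of the luteal differences, a batch shared by the number 7 libraries is argued against. The luteal list differed by log2 3.44 between testosterone 7 and control 7. A number 7 batch in other respects stays open, as structured RNA made up 0.263% of control 7 and 0.331% of testosterone 7, above the other adult libraries. Testosterone as the whole cause is argued against by a range of 3.84 among the controls alone. Without OXT, the other 12 luteal genes ranked the libraries only weakly alike (Kendall's W 0.252). This was above the 95th percentile of 1000 random lists (0.196), though the highest random list reached 0.445. STAR, also named after its values were seen, is among the 12, so the ranking is not independent of the pattern. A corpus luteum in some ovaries at collection may be the source, and the cycle stage of the ewes is not given in the sources used here.

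ENSOARG00000020231 and ENSOARG00000020142 separated the adult groups without overlap. They were among 111 of 15757 genes that did so with all 8 libraries (0.70%, against 2.86% by chance). Another was ENSOARG00000010762, chosen after its values were seen, with 310 to 395 in controls and 703 to 1364 after testosterone. In the joined fits it passed with DESeq2 but not with limma or edgeR. The lowest testosterone value of ENSOARG00000020231 was 11.5-fold above its highest control, while 0 of 13 cell type lists separated the groups. This argues against the share of a listed cell type as its whole cause, so far as a list follows that share. Smaller shifts of cell types were not tested. For reads taken from another counted gene, 0 genes were lower in all 4 testosterone libraries with a loss between 0.5 and 2 times the gain. A source that varied more between libraries, or several sources, could be missed. For ENSOARG00000020142, an inherited sequence variant is a candidate explanation, as 1 of 6 fetal libraries, testosterone 3, had at least 10 reads (138, against at most 2 in the others). For ENSOARG00000020231, the treatment, kinship of the animals, reads from such a source and copies of the gene that were not counted stay open.

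CYP11A1 and CYP17A1 were lower in testosterone fetuses. The other 14 theca genes had a median log2 change of -0.17 (SD 0.33), so the rest of the list did not fall as far. This does not decide on a smaller share of steroidogenic cells. Members of the list that other cells of the whole ovary also express would hide such a loss. A single library is argued against, since the weaker change was still -1.86 with any 1 library left out, and so is scaling, with -2.25 under quantile normalization or TMM. Lower expression of these 2 genes under testosterone and fewer cells that express them both remain as hypotheses, with limma adjusted p = 0.223 and 0.237 over all genes.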

How the results depend on the processing

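The joined fits of all 8 adult libraries, mixed fry and the edgeR interaction were chosen only after the result was seen; the other alternatives were set before. Of 878 alternative values for the 55 fetal genes the rule selects, 872 kept their direction. So did 491 of 507 for 32 genes in the first adult table and 339 of 361 for 23 in the second. Some of these could not turn: other filters and dropping the mean-variance trend leave the fitted log2 change of a gene as it is. The block does so too in the fetal and first adult tables. Many of the genes were also picked by p in the same libraries, so these shares do not measure robustness. CORIN and EFHB passed under 11 of 16 alternatives and PLCXD3 under 10, with adjusted p up to 0.116, 0.190 and 0.190. Among the passed ones is the fit without the filter, which is the main fit again, since all 16513 fetal genes met the filter. Sample numbers were not taken as pairs: in fetuses the deviations of same-numbered samples correlated at 0.13, 0.0093 and 0.40, and only control 3 and testosterone 3 were each most alike to their own number.

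The 3 fetal genes became 261 with DESeq2, 17 with array weights, 10 with the replicate block, 20 at a threshold of 0.1, and 0 to 13 without 1 library. The 6 fetal lists became 0 with an estimated correlation, 0 with fry and 8 with mixed fry, and 6 to 12 without 1 library. The 1 gene of each adult table became 4 (first) and 5 (second) with DESeq2, 0 with edgeR, 0 with the replicate block, and 0 to 0 without 1 library. With all 8 adult libraries it became 2 by limma, 7 by DESeq2, 2 with the luteal covariate and 0 with the replicate block. The 14 and 5 adult lists became 0 with an estimated correlation, 0 with fry and 0 with mixed fry, 3 to 19 and 8 to 19 without 1 library, 10 in the second with the replicate block, 7 with all 8 libraries, and 9 with all 8 but control 4. The 0 genes differing between ages became 1 by edgeR interaction and 1 with all 8 libraries by either tool, and 0 to 1 without 1 library for the first table. Genes at both ages at an unadjusted p under 0.05 were 7 higher and 2 lower for the first table and 9 and 3 for the second. The cause was not tested.

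Direction turned for fetal STAR (0.0053) and ESR2 (0.091) with array weights, and without 1 library (-0.18 to 0.056 and -0.23 to 0.23). In the first adult table CYP11A1 was 0.31 with DESeq2 and 0.32 with edgeR, and ESR1 -0.036 and -0.032. Without 1 library FSHR ran from -0.37 to 3.11, ESR1 from -0.25 to 0.39, STAR from -2.55 to 0.57, CYP11A1 from -1.90 to 1.08 and CYP17A1 from -0.84 to 3.69. In the second table DESeq2, edgeR and the replicate block gave FSHR -0.29, -0.23 and -1.53, STAR 0.32, 0.37 and 0.42, and CYP11A1 0.41, 0.46 and 0.25. INSR was -0.12 with the block and ESR1 0.49 with array weights. Without 1 library FSHR ran from -1.21 to 2.86, CYP17A1 from -1.36 to 3.52, ESR1 from -0.50 to 0.39, STAR from -2.46 to 0.85 and CYP11A1 from -2.09 to 0.83. The cause was not tested.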

Other observations

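The splits of the samples were set in advance except those of all 8 adult libraries, whose joining was chosen only after the result was seen. Oocyte and germ cell genes did not move together in the fetal libraries. Oocyte markers stood at 0.79 in control 3 and 0.38 in testosterone 3, relative to the mean of the 6 libraries, and between -0.41 and -0.15 in the other 4, while germ cell and meiosis genes stood at -0.60 and -0.58 in the same pair. No comparison between such libraries was made.

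Follicle genes differed between single adult libraries. The single genes named in this paragraph were chosen after their values were seen. INHA, the inhibin alpha subunit of granulosa cells, had 9215 in control 7 and 5012 in control 5 but 135 in control 4, and IHH, a granulosa signal, had 1172, 1259 and 2.36 there. INSL3, a theca hormone, had 29961 in testosterone 6 and 135 in testosterone 7. The list of macrophage and myeloid markers, which shares no gene with the luteal list, stood at 2.03 in control 6, 1.97 in testosterone 4 and 2.31 in testosterone 7, relative to the mean of the 8 libraries, and between -2.25 and -0.50 elsewhere. Among mitochondrial genes, COX1 had 268 in testosterone 4 and at least 12347 in the other adult libraries, and ATP8 had 69.9 in control 5, 240 in control 7 and 63.8 in fetal testosterone 2. Reads of structured RNA genes made up 0.263% of control 7 and 0.331% of testosterone 7, against 0.058% to 0.138% in the other adult libraries.

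In each 3 against 3 comparison there are 10 splits of the libraries, too few for a share under 0.05. The real fetal count was 3 genes with limma and the highest other 29, and with DESeq2 261 and 264, in the split of controls 1 and 2 and testosterone 1 from the rest. The real adult counts were 1 and 1, and the highest others 1216 (controls 4 and 6 and testosterone 4 from the rest) and 288 (controls 4 and 6 and testosterone 7 from the rest), several times the real count, which points to a structure of the samples. For lists the real counts were 6, 14 and 5 and the highest others 14, 23 and 23. At least as many lists as in the real split passed in 8, 5 and 10 of the 10 splits, the real one included. With all 8 adult libraries, 4 of 35 splits gave as many as the real 2 genes (highest other 2991) and all 35 gave as many as the real 7 lists (highest other 23), so chance is not excluded. For the difference between ages the real count was 0 genes with either adult table, which all 100 splits reach by definition, so these splits say nothing about chance (highest others 64 and 1).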
